A study of Mus musculus with 18 samples.

How the data were processed

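Total RNA of 18 lymphomas from Atm, mTerc and p53 triple knock-out mice and of a common thymus reference was hybridised to 2-colour Agilent mouse arrays. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and purified on columns, and each lymphoma was measured with a dye swap. The labelling protocol names arrays for comparative genomic hybridisation and the series title speaks of DNA, while the molecule, the extraction and the series type are those of RNA. Y-linked and tissue-specific transcripts differed by large factors, as values of RNA do, and the values were treated as RNA. Feature extraction, normalization and the way in which the dye-swap pair was combined are not given in the sources used here.

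The deposited table holds 1 column of log10 ratios per lymphoma and 41175 probes. The base is not stated. Base 10 was inferred because the software of the array maker writes log10 ratios. The Y-linked Eif2s3y lay more than 2 deposited units below 0 in 7 of 18 lymphomas, and its lowest value would be 5.04-fold lower in base 2 and 216-fold lower in base 10, which does not settle the base. Every fold given depends on that inference. All values were multiplied by 3.3219 to give log2 ratios. The deposited log10 columns have medians between -0.0114 and 0.0370, and no further centring or scaling was applied. Whether the authors had centred the arrays is not known. The direction is unstated too. By a rule fixed beforehand, lymphoma over reference was called likely because Atm and Terc were then lower in at least 14 of 18 lymphomas. Under that rule thymic epithelium genes were the next basis, needed only if Atm and Terc had not settled it. They were lower as well. The lymphomas keep the numbers that the labels give them.

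Probes were named through the platform annotation, which can be old. Of the 41175 probes, 31700 carry 1 gene symbol, 47 carry several and 9428 have none here. Of the 31700, 31564 matched a gene by Entrez identifier in a RefSeq table of assembly GRCm38.p6, which changed the symbol of 0 probes. That table was used only for names, chromosome and gene order, and no coordinates are given, since the build behind the array design is not given in the sources used here. Probes needed a value on at least 14 of 18 arrays, which 37295 did. A gene's value is the mean of its probes that name only that gene, giving 18147 genes, of which 17001 have a value in all 18 lymphomas and 7702 rest on more than 1 probe. For 623 genes, probes passed in both directions. Probes without a gene name were tested apart, and 3902 of 7734 differed from the reference, 313 at least 2-fold higher and 595 at least 2-fold lower. No column of other samples was present.

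The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Because no control sample was hybridised against the reference, the reference counts as 1 control and its own spread is not in the test. Genes changed at least 2-fold were counted separately. Gene lists were tested with camera in limma, with a preset correlation of 0.01 over 18147 genes and with an estimated correlation over the 17001 complete genes, and with fry. Adjustment was over 38 lists. A further list of sex-linked genes served as a sample check and was not tested. Of 541 genes in the lists, 5 belong to more than 1 list. Errors are SD over lymphomas. The signal over background of single spots was not used here, so the number of arrays is the limit on precision that can be given.

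The fit was tested on simulated data, 20 draws of 18147 genes with the spread of the real arrays, in which 200 genes were shifted. A shift of 0.5 on the log2 scale was recovered for a median of 48% of genes and a shift of 1 for 86.5%. A draw gave a median of 3.5 false calls and at most 37, and a shifted list of genes drawn at random was recovered in 20 of 20 draws. For the chromosome medians over 18034 genes in a random order, a planted shift of 0.2 was estimated at 0.202, and 5.85% of the other medians had a p under 0.05. Neither the random list nor the random order keeps the correlation within real lists or between neighbours, so these checks leave out its effect. Only 200 genes were shifted per draw, while 10480 of 18147 passed in the data. The adjusted threshold depends on that share, so recovery and the number of false calls in the data can differ from these.

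Genes named in the text follow a rule fixed before the data were examined, although not every gene it takes is named. It takes the targeted genes, the 12 named genes with the largest mean increase and the 12 with the largest decrease among those passing, at least 2-fold and with the same sign in at least 16 of 18 lymphomas, up to 4 members of each list with the smallest adjusted p, all members of lists of 12 or fewer measured genes, and the 10 genes with the largest SD. Hes1, Dtx1, Notch3, Nrarp, Ptcra, Il2ra, Ikzf1, Cdkn1a, Cd8a, Cd4, Dntt, Asns, Tert, Zap70 and Cd3e come from the fixed lists but were chosen after their values were seen, as were Krt5, Acta1, the genes given with runs on chromosomes and the lymphomas singled out. The lists, also fixed beforehand, cover pathways and markers of the cell types that thymus or lymphoma tissue could hold.

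For position, 18034 genes were ordered along chromosomes and 113 were not placed. Each gene's median over lymphomas was subtracted, and the median per lymphoma and chromosome was compared with 10000 permutations of genes over chromosomes, adjusted over 360 medians. Correlations of neighbouring genes and runs of 11 genes used 16917 complete genes with each array centred, and 100 shuffled gene orders. A run joins windows whose median lies beyond every window of that lymphoma in the 100 orders and whose starts lie at most 11 genes apart. Windows that do not pass can therefore lie inside a run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

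Alternatives fixed before the data were examined covered centring, scaling and quantile normalization of arrays, the filter on missing values, the rule for several probes, robust eBayes, array weights, an ordinary one-sample statistic, the signed-rank test, single probes, other fold and p thresholds, other list tests and leaving out each lymphoma. Leaving out lymphomas 7, 12 and 14, or 1, 2, 3, 5, 15, 17 and 18, was added after seeing the data.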

Results

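RNA from 18 lymphomas of mice lacking Atm, mTerc and p53 together was compared with RNA of mouse thymus on 2-colour Agilent oligonucleotide arrays. Atm is a kinase that signals DNA breaks, mTerc (Terc) is the RNA template of telomerase, and p53 is the transcription factor at the centre of the DNA damage response. The reference was thymus RNA of healthy 3-week-old mice heterozygous for p53, and each lymphoma was hybridised with a dye swap and carries 1 value per probe. All 18 lymphomas form 1 group, so the comparison the design implies is lymphoma against thymus, gene by gene and by gene group. No lymphoma of another genotype and no knock-out thymus without lymphoma was measured. Effects of the knock-outs, of the tumour and of cell content can therefore not be told apart. Nothing in the labels says that the lymphomas came from separate mice, so the p-values measure only the spread between these samples. Between 2.27% and 7.79% of the probes had no value on an array, and the median log2 ratio per array lay between -0.04 and 0.12. The number of arrays limits the precision, and the median SD of a gene over the lymphomas was 0.54 on the log2 scale.

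In the likely direction of the ratio, which was chosen by them, the targeted genes that were analysed were lower in the lymphomas than in thymus. Terc fell by 1.47 on the log2 scale (SD 0.58, n = 18), 2.76-fold, and was lower in 18 of 18 lymphomas (limma adjusted p = 3.64e-08). Atm fell by 0.65 (SD 0.53, n = 18), 1.57-fold, and was lower in 17 of 18 lymphomas (limma adjusted p = 1.59e-04), with a ratio of 0.56 in lymphoma 15. The p53 transcript was not analysed here. The labels do not state which RNA is in the numerator of the ratio. Lymphoma over thymus is the likely direction, by a rule fixed before the data were examined, because it places the deleted genes below thymus. Whether the Atm and Terc probes lie within the deleted parts of the genes is not known, so their remaining signal checks no single label. The 2 Terc probes differed, with means of -2.66 ± 1.08 (SD, n = 18) and -0.27 ± 0.64, and on the second alone Terc did not pass (adjusted p = 0.119).

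The genes with the largest mean increase included receptors, secreted proteins and a metabolic enzyme. Fbp1, an enzyme of gluconeogenesis, had the largest increase, 4.18 ± 1.88 on the log2 scale (SD, n = 18) or 18.2-fold, and was higher in 17 of 18 lymphomas (limma adjusted p = 7.59e-08). Notch1, the receptor that commits progenitors to the T lineage, was 9.43-fold higher (3.24 ± 2.22, higher in 16 of 18, adjusted p = 1.23e-05). Pdgfrb, a platelet-derived growth factor receptor of mesenchymal cells, was 7.68-fold higher (2.94 ± 1.34), and Crnde, a long non-coding RNA, was 8.73-fold higher (3.13 ± 0.74). Both were higher in 18 of 18 lymphomas. The other genes among the 12 with the largest increase were Sertad4 (3.35 ± 1.42), F2 (3.32 ± 2.08), which encodes prothrombin, Esm1 (3.26 ± 1.44), an endothelial proteoglycan, Fam183b (3.08 ± 1.93), Greb1 (2.98 ± 1.47), Wdr25 (2.87 ± 1.46), Cthrc1 (2.86 ± 1.88), a secreted matrix protein, and Cnnm1 (2.84 ± 1.67).

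The 12 genes with the largest decrease included genes of neutrophils, epithelium and brown fat. S100a8 and S100a9, the subunits of the neutrophil protein calprotectin, lay at -5.55 ± 2.37 (SD, n = 18) and -5.54 ± 2.27, 46.7-fold and 46.6-fold lower, and were lower in 18 of 18 lymphomas (adjusted p = 4.22e-08 and 2.61e-08). Camp, the antimicrobial peptide of neutrophil granules, was 27.5-fold lower (-4.78 ± 1.42). Ccl25, a chemokine of thymic epithelium, was 27.0-fold lower (-4.76 ± 1.31, lower in 17 of 18), and the simple-epithelium keratin Krt18 was 30.9-fold lower (-4.95 ± 2.20). Cidea, a lipid droplet protein of brown fat, fell by 4.90 (SD 1.76), and Cox8b, a cytochrome oxidase subunit of muscle and brown fat, was at -4.72 ± 2.50. The remaining genes among the 12 with the largest decrease were Cyp2a5, Reg3b, an antimicrobial lectin, Aoc1, a diamine oxidase, Dmrt2 and the Y-linked Eif2s3y, whose means lay between -5.47 and -4.90.

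**Figure D1:**
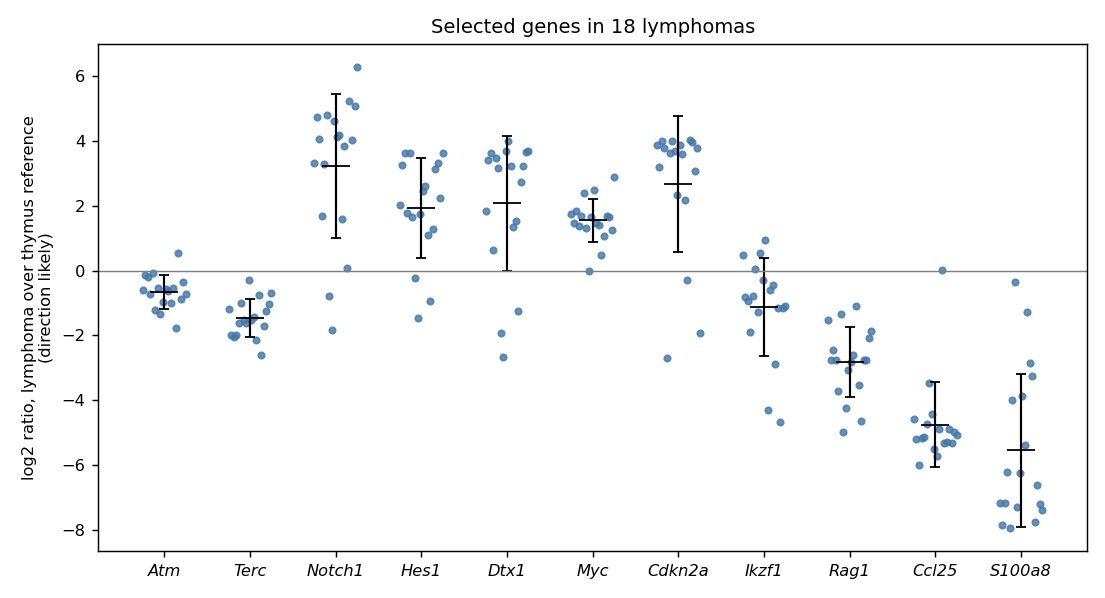
Log2 ratio of lymphoma over thymus reference for 11 genes, with a dot for each of the 18 lymphomas and a bar for the mean ± SD. Terc lies below 0 in 18 lymphomas, Notch1 above 0 in 16 and S100a8 below 0 in 18, while Cdkn2a ranges from -2.71 to 4.02.

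Of 18147 genes tested, 10480 differed from the reference at an adjusted p under 0.05 (limma, ratio against 0), 5419 higher and 5061 lower. A change of at least 2-fold was found for 2759 of them, 781 higher and 1978 lower, so 28.3% of the larger changes were increases, or 71.7% if the direction of the ratio, which is only likely, were turned. In at least 16 of the 18 lymphomas, 2883 genes were above and 3077 below the reference. The reference is the only control RNA, so the test leaves out the spread between control animals. Lymphomas 1, 2, 3, 5, 15, 17 and 18 carried few macrophage markers, and without them 7306 genes differed (3556 higher and 3750 lower). Without lymphomas 7, 12 and 14, which correlated least with the others, 11261 genes differed (5758 higher and 5503 lower). The genes changed at least 2-fold numbered 2207 without the first set of lymphomas and 3362 without the second. Both exclusions were chosen after seeing the data.

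Of 38 fixed gene lists, 21 stood apart from the other genes in the camera test with a preset correlation of 0.01, 7 higher and 14 lower. None of the 38 held at an adjusted p under 0.05 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. In the fry test, which asks whether the genes of a list move on balance in 1 direction and makes no comparison with other genes, 28 lists passed. Counts adjusted over the list alone are given where they differed from those over all genes tested.

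Genes of cell growth and biosynthesis were higher in the lymphomas. In the list of serine and one-carbon metabolism, which feeds nucleotide synthesis, 12 of 13 measured genes rose and none fell. Shmt2, the mitochondrial serine hydroxymethyltransferase, rose 4.81-fold (2.27 ± 0.63, SD, n = 18), Slc7a5, a transporter of large neutral amino acids, rose 4.05-fold (2.02 ± 0.64), and Phgdh, which opens serine synthesis, rose 3.11-fold (1.63 ± 0.50). These were higher in 18 of 18 lymphomas. Asns, asparagine synthetase, rose 7.16-fold (2.84 ± 1.54). The camera adjusted p was 5.98e-07, and the adjusted p = 0.291 with an estimated correlation. Of 16 ribosome biogenesis genes, 12 rose and none fell, among them Bop1 (1.23 ± 0.36), Rrp9 (1.32 ± 0.49) and the nucleolar methyltransferase gene Fbl (0.89 ± 0.27), each higher in 18 of 18 lymphomas (camera adjusted p = 1.19e-05, and adjusted p = 0.291 with an estimated correlation). In glycolysis, 12 of 14 genes rose, and 13 when adjusted over the list alone, with Pfkl at 1.77 ± 0.68, Pkm at 1.74 ± 0.80 and Tpi1 at 1.38 ± 0.52 (camera adjusted p = 7.04e-05, and adjusted p = 0.307 with an estimated correlation).

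In the DNA replication list, 15 of 24 genes rose and 1 fell (17 and 1 adjusted over the list alone). Thymidine kinase Tk1 (1.05 ± 0.35) and the helicase subunits Mcm2 (1.04 ± 0.49) and Mcm3 (0.99 ± 0.50) were among them (camera adjusted p = 1.36e-04, and adjusted p = 0.467 with an estimated correlation). Of 13 genes of cholesterol synthesis, 9 rose and none fell, including Mvd (1.80 ± 0.85) and Lss (1.77 ± 1.13), both higher in 18 of 18 lymphomas (camera adjusted p = 0.00258, and adjusted p = 0.545 with an estimated correlation). The list mean lay between 1.15 and 2.26 in the 7 lymphomas with few macrophage markers and between -0.12 and 0.57 in the other 11. Without those 7, Lss was at 1.01 and the list no longer passed (adjusted p = 0.151). In the unfolded protein response, 7 of 14 genes rose and 1 fell, among them Chac1 (2.99 ± 1.76), Trib3 (1.73 ± 1.23) and Atf4 (0.90 ± 0.59), which also answer amino acid shortage. Its camera adjusted p was 0.0262, and the adjusted p = 0.522 with an estimated correlation. Leaving out lymphoma 14 alone moved the preset value to 0.0517.

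Genes of normal thymocytes and mature T cells were lower. Of 17 genes of cortical double-positive thymocytes, 15 fell and none rose. Rag1, a subunit of the V(D)J recombinase, fell by 2.83 (SD 1.08, n = 18), the chemokine receptor gene Ccr9 by 3.14 (SD 1.21), and Cd1d1, which presents lipids to natural killer T cells, by 2.10 (SD 0.54). All were lower in 18 of 18 lymphomas. The coreceptor genes Cd8a (-2.56 ± 1.35) and Cd4 (-1.01 ± 0.66) fell as well. The camera adjusted p was 3.08e-06, and the adjusted p = 0.291 with an estimated correlation. Of 15 genes of mature T cells, 8 fell and none rose, with Cd69, an early activation antigen, at -3.51 ± 1.10, Ms4a4b at -3.85 ± 1.34, and Ccr7, which guides T cells to lymph nodes, at -2.64 ± 0.91 (camera adjusted p = 4.75e-04, and adjusted p = 0.291 with an estimated correlation).

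Of 17 cytokine and chemokine receptor genes, 10 fell and none rose, including Tnfrsf4 (-1.40 ± 0.52) and Il21r (-2.27 ± 1.09) besides Ccr7 and Ccr9 (camera adjusted p = 5.09e-04, and adjusted p = 0.291 with an estimated correlation). In T cell receptor signalling, 10 of 17 genes fell and 1 rose. The costimulatory receptor gene Cd28 (-1.78 ± 0.99), the adaptor gene Lcp2 (-1.04 ± 0.57) and Trat1 (-2.19 ± 1.52) fell, while the kinase gene Zap70 rose (0.57 ± 0.97, adjusted p = 0.0290). The Zap70 call was lost without lymphoma 2, 10 or 18, with adjusted p-values of 0.0516, 0.0526 and 0.0571, and without the 7 lymphomas low in macrophage markers (0.371). Cd3e, a constant chain of the receptor complex, was at 0.21 ± 0.78 and did not pass (adjusted p = 0.326), but did with 1 probe per gene (0.69, adjusted p = 2.47e-04), with array weights (0.37, adjusted p = 0.0220), without lymphoma 14 (0.33, adjusted p = 0.0497) and without lymphomas 7, 12 and 14 (0.42, adjusted p = 0.0163). The list had a camera adjusted p of 0.00696, and an adjusted p = 0.581 with an estimated correlation. Without lymphomas 7, 12 and 14 it no longer passed (adjusted p = 0.108), and the list mean in lymphoma 14 was -3.08. Of 14 immediate early and stress genes, 7 fell and none rose, with Nr4a1, an early target of the T cell receptor, at -2.79 ± 1.35 and Junb at -1.23 ± 0.67 (camera adjusted p = 0.00662, and adjusted p = 0.336 with an estimated correlation).

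Markers of thymic epithelium and of some other cell types were lower too, while several cell type lists did not pass. In thymic epithelium, 15 of 16 genes fell, and all 16 when adjusted over the list alone, led by Ccl25, the thymoproteasome subunit gene Psmb11 (-4.30 ± 1.41), the thymus-specific serine protease gene Prss16 (-4.18 ± 1.40) and Tbata (-4.09 ± 1.54). Each of these was lower in 17 of 18 lymphomas (camera adjusted p = 5.38e-08, and adjusted p = 0.291 with an estimated correlation). Thymic epithelium genes were the next basis for the direction of the ratio, so the direction of this list is no independent check of it. All 13 genes of dendritic cells and MHC class II fell, including the class II chain gene H2-Aa (-3.23 ± 1.63), its transactivator gene Ciita (-2.70 ± 1.18) and Siglech (-1.80 ± 0.71), with a camera adjusted p of 3.08e-06 and an adjusted p = 0.291 with an estimated correlation. Of 10 neutrophil genes, 8 fell and none rose, and adjusted over the list alone 9 fell and 1 rose. Ngp was at -3.55 ± 0.74 and Retnlg at -2.83 ± 1.02, both lower in 18 of 18 lymphomas (camera adjusted p = 1.09e-05, and adjusted p = 0.291 with an estimated correlation).

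All 9 adipocyte genes fell, with Ucp1, the uncoupling protein of brown fat, at -4.44 ± 2.12, the hormone gene Adipoq at -3.54 ± 1.73 and Retn at -2.19 ± 0.73 (camera adjusted p = 1.39e-05, and adjusted p = 0.291 with an estimated correlation). Of 8 plasma cell genes, 6 fell, among them Jchain (-3.34 ± 1.59), the joining chain of secreted antibodies, and Tnfrsf17 (-2.73 ± 1.14), while Sdc1, a syndecan also made by other cells, rose (2.16 ± 0.71, higher in 18 of 18). Of the 6 that fell, Derl3 lost its call with quantile normalization (limma adjusted p = 0.0530) and without several single lymphomas, such as lymphoma 2 (0.0772). Irf4 lost its call without lymphoma 1, 9 or 18 (limma adjusted p = 0.0503, 0.0508 and 0.0525). The plasma cell list had a camera adjusted p of 0.0262, and an adjusted p = 0.379 with an estimated correlation. Of 9 hepatocyte genes, 5 fell, including Cyp2e1 (-3.26 ± 1.05) and Fgb (-2.16 ± 0.83) (camera adjusted p = 0.0234, and adjusted p = 0.336 with an estimated correlation). Without the 7 lymphomas low in macrophage markers, the plasma cell and hepatocyte lists no longer passed (adjusted p = 0.0583 and 0.117). Of 18 interferon response genes, 12 fell and none rose, and 13 fell when adjusted over the list alone, with Ifit1 at -1.66 ± 1.55 and Psmb9 at -0.74 ± 0.61 (camera adjusted p = 0.00445, and adjusted p = 0.545 with an estimated correlation). The mean of that list was above 0 in lymphomas 3 (1.06), 14 (0.88), 7 (0.49) and 12 (0.37).

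**Figure D2:**
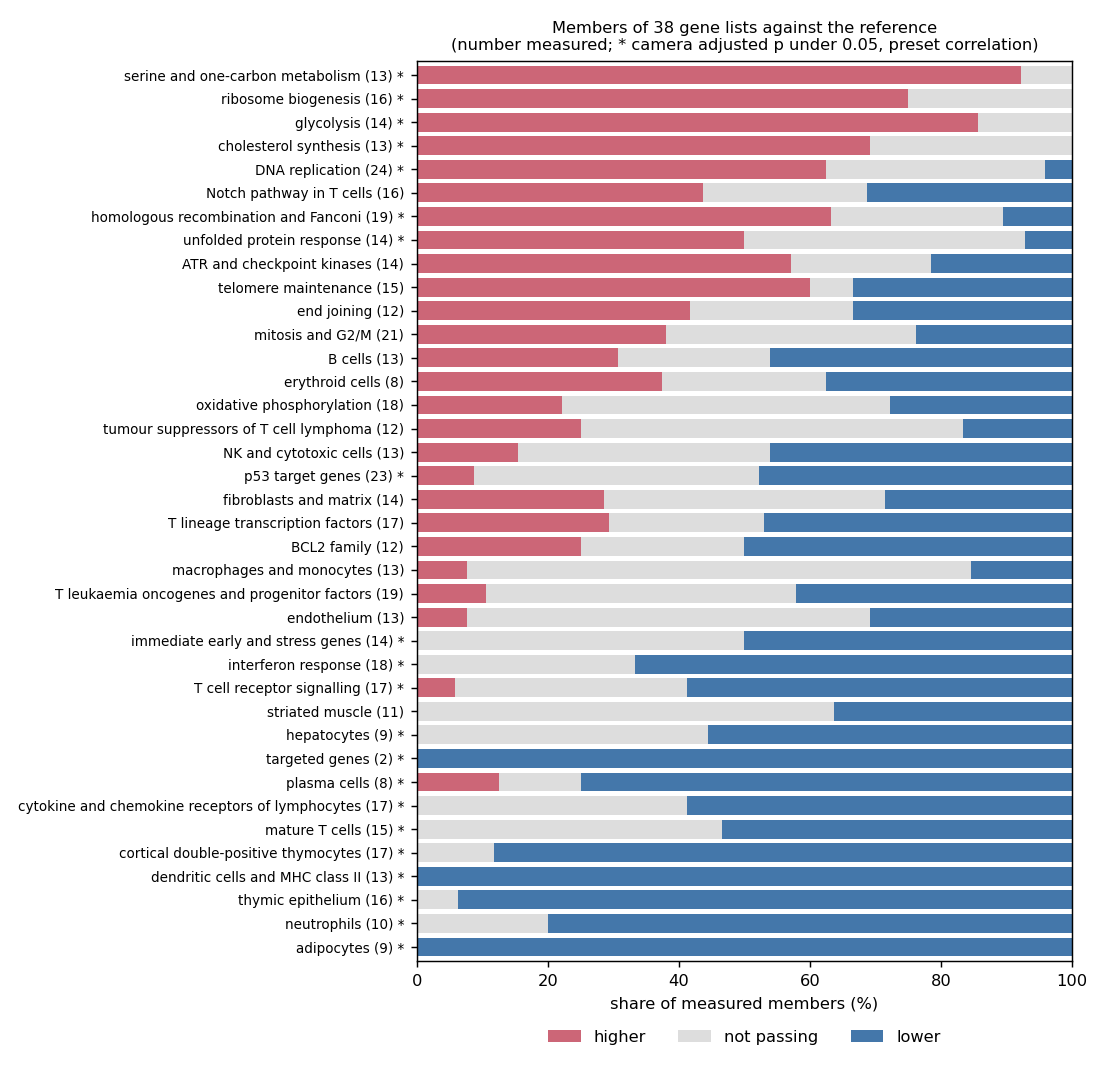
Share of the measured genes of each of 38 fixed lists, in percent, that were higher, lower or not passing at an adjusted p under 0.05 in lymphoma against thymus, with an asterisk for lists that passed the camera test with the preset correlation. For serine and one-carbon metabolism 12 of 13 genes were higher, and for dendritic cells and MHC class II 13 of 13 were lower.

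Among known p53 target genes, 11 of 23 fell and 2 rose. The death receptor gene Fas was 7.42-fold lower (-2.89 ± 0.96, lower in 18 of 18, adjusted p = 3.14e-09), Perp, an apoptosis-associated membrane protein, was 16.5-fold lower (-4.04 ± 2.17, lower in all but lymphomas 7 and 12), and Sesn1, a stress-induced sestrin, was 2.01-fold lower (-1.01 ± 0.42, lower in 18). Cdkn1a, which encodes the cell cycle inhibitor p21, went the other way (1.12 ± 1.26, higher in 15 of 18, adjusted p = 0.00200). Lymphomas 7 and 12 also had the highest means of the thymic epithelium list, so epithelial content and loss of p53 are not separated for Perp. The p53 target list had a median of -0.23 and a mean of -0.77. Its camera adjusted p was 0.0143, and the adjusted p = 0.291 with an estimated correlation. The direction of the ratio was chosen by the 2 targeted genes, so the direction of their list is no independent result. That list had a camera adjusted p of 0.0411, and an adjusted p = 0.291 with an estimated correlation. Its preset call was lost without lymphoma 7 (adjusted p = 0.0634) or lymphoma 12 (0.0528), with quantile normalization (0.0663), with arrays scaled (0.0644), with genes that have a value on all arrays (0.0527), with 1 probe per gene (0.313) and with camera on ranks (0.0619).

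Among DNA repair genes, homologous recombination and the Fanconi pathway were higher, with 12 of 19 genes risen and 2 fallen. Brca1 (0.84 ± 0.45), Brca2 (1.07 ± 0.60), their partner gene Palb2 (0.86 ± 0.44) and Rad54l (0.82 ± 0.46) each rose in at least 17 of 18 lymphomas (camera adjusted p = 0.00492, and adjusted p = 0.522 with an estimated correlation). End joining genes went both ways, with 5 of 12 risen and 4 fallen (6 and 4 adjusted over the list alone). The ligase cofactor gene Xrcc4 fell (-0.90 ± 0.38, lower in 18 of 18) and so did the polymerase gene Polm (-1.19 ± 0.72), while Parp1 rose (1.22 ± 0.68), and the list did not pass (camera adjusted p = 0.819). Of 14 genes of ATR and the checkpoint kinases, 8 rose and 3 fell, with Timeless at 1.76 ± 0.75, Atrip at 0.91 ± 0.39 and Rad9a at -0.67 ± 0.35. That list did not pass (camera adjusted p = 0.130), but did without lymphoma 14 (adjusted p = 0.0476). Of 15 telomere maintenance genes, 9 rose and 5 fell (camera adjusted p = 0.269). The telomerase components Nhp2 (0.82 ± 0.28), Nop10 (0.66 ± 0.43) and Tert (0.73 ± 0.68) and the telomere helicase gene Rtel1 (0.86 ± 0.41) rose, whereas the telomere-binding factor gene Terf1 fell (-0.72 ± 0.41). Tert was at 0.46 without the 7 lymphomas low in macrophage markers. Of 21 mitosis genes, 8 rose and 5 fell (camera adjusted p = 0.297), with the kinase genes Aurka (0.79 ± 0.31) and Plk1 (0.53 ± 0.19) higher and Nusap1 (-0.98 ± 0.54) lower in 18 of 18 lymphomas.

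In the Notch pathway, the receptor and several targets rose while the list as a whole did not stand apart. Notch1 exceeded 2-fold in 15 of 18 lymphomas. The target genes Hes1 (1.93 ± 1.53, adjusted p = 6.59e-05), a transcriptional repressor, and Dtx1 (2.08 ± 2.09, adjusted p = 6.65e-04) were each higher in 15 of 18, and Notch3 was higher in 16 (1.30 ± 1.12). Dll1, a Notch ligand, fell (-2.39 ± 1.60), and so did the protease gene Adam10 (-0.62 ± 0.26, lower in 18 of 18). Il2ra (0.77 ± 2.12) and Ptcra (0.60 ± 2.30) did not pass. With 1 probe per gene Il2ra did (1.38, adjusted p = 0.0204), and so did Ptcra with array weights (1.06, adjusted p = 0.0300) or without lymphomas 7, 12 and 14 (1.22, adjusted p = 0.0152). In all, 7 of 16 genes rose and 5 fell (7 and 6 adjusted over the list alone), with a camera adjusted p of 0.888. Without the 7 lymphomas low in macrophage markers, Dll1 was at -1.52, Hes1 at 1.21 (adjusted p = 0.0286) and Dtx1 at 1.36, which no longer passed (adjusted p = 0.102).

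Among oncogenes of T cell leukaemia and progenitor factors, Myc, a driver of growth and biosynthesis, was 2.92-fold higher (1.55 ± 0.66, higher in 17 of 18, adjusted p = 7.31e-08). It was among the 2 of 19 genes that rose, while 8 fell, including Hoxa7 (-1.87 ± 0.83) and Bcl11a (-1.95 ± 0.94). This list did not pass (camera adjusted p = 0.0565), but did without lymphoma 10 (adjusted p = 0.0444), 12 (0.0323) or 14 (0.0154). Among tumour suppressors of T cell lymphoma, Cdkn2a, which encodes the inhibitors p16 and p19Arf, was 6.38-fold higher (2.67 ± 2.10, higher in 15 of 18, adjusted p = 5.60e-05). It lay between 2.19 and 4.02 in those 15 and at -2.71, -0.28 and -1.93 in lymphomas 5, 13 and 18. In this list 3 of 12 genes rose and 2 fell, Cdkn1b (-0.58 ± 0.31) among the latter, the median was -0.04 and the mean 0.21, and the camera adjusted p was 0.968. Of 17 T lineage transcription factors, 5 rose and 8 fell (camera adjusted p = 0.412), with Runx1 at 1.07 ± 0.58, Myb at -1.41 ± 1.28, and Egr2, induced by receptor signals, at -4.14 ± 1.31. In the BCL2 family, 3 of 12 genes rose and 6 fell (camera adjusted p = 0.186), and the survival factor gene Bcl2l1 (-0.98 ± 0.50) fell in 17 of 18 lymphomas. Of those that rose, Bid lost its call with quantile normalization (limma adjusted p = 0.0693) and without several single lymphomas, such as lymphoma 9 (0.0838).

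The remaining lists did not pass the camera test. Of 13 B cell genes, 4 rose and 6 fell, with Ms4a1 at -2.73 ± 1.46 (camera adjusted p = 0.317, median 0.06, mean -0.63). Of 13 NK and cytotoxic cell genes, 2 rose and 6 fell, with Klrd1 at -3.36 ± 1.79 (adjusted p = 0.166). That list passed without lymphomas 7, 12 and 14 (adjusted p = 0.0326). Of 8 erythroid genes, 3 rose, among them the transferrin receptor gene Tfrc (1.83 ± 1.08), and 3 fell, among them the globin gene Hba-a1 (-3.08 ± 1.68) (adjusted p = 0.984). Of 14 fibroblast and matrix genes, 4 rose, including Pdgfrb and Fbln1 (2.47 ± 1.15), and 4 fell (adjusted p = 0.984). Among 13 endothelial genes, 1 rose, Egfl7 (median 0.96, higher in 17 of 18), and 4 fell, or 3 adjusted over the list alone (adjusted p = 0.280). Of 11 striated muscle genes, 4 fell and none rose, with Actn3 at -2.06 ± 1.72 (adjusted p = 0.173). Of 18 oxidative phosphorylation genes, 4 rose, with Cyc1 at 0.99 ± 0.33, and 5 fell (adjusted p = 0.951). Of 13 macrophage genes, 1 rose and 2 fell (adjusted p = 0.412), and these differed widely between lymphomas.

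The 10 genes that varied most between lymphomas included markers of macrophages, blood vessels and matrix. The SD over the 18 lymphomas was 3.93 for the chemokine gene Ccl8, 3.63 for Pf4, 3.56 for the lectin gene Clec7a, 3.55 for Sparcl1, 3.36 for the basement membrane gene Nid1, 3.28 for Selenop, 3.27 for the protease gene Ctss, 3.14 for Cd5l, 3.13 for Wfdc17 and 3.12 for Ctsh. The mean of the macrophage list lay between -2.88 and -1.99 in lymphomas 1, 2, 3, 5, 15, 17 and 18 and between -0.01 and 2.54 in the other 11. The endothelial list mean lay between -1.92 and -1.58 in those 7 and between -0.89 and 2.71 in the other 11, whereas the fibroblast list mean overlapped, from -2.19 to 0.97 and from -0.49 to 3.61. The adipocyte and dendritic cell list means were also lower in each of the 7 than in each of the other 11. Correlation between pairs of lymphomas over all probes ranged from 0.0674 to 0.816 with a median of 0.572 over 153 pairs, and no pair shared identical values. Genes are not independent replicates in these correlations.

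**Figure D3:**
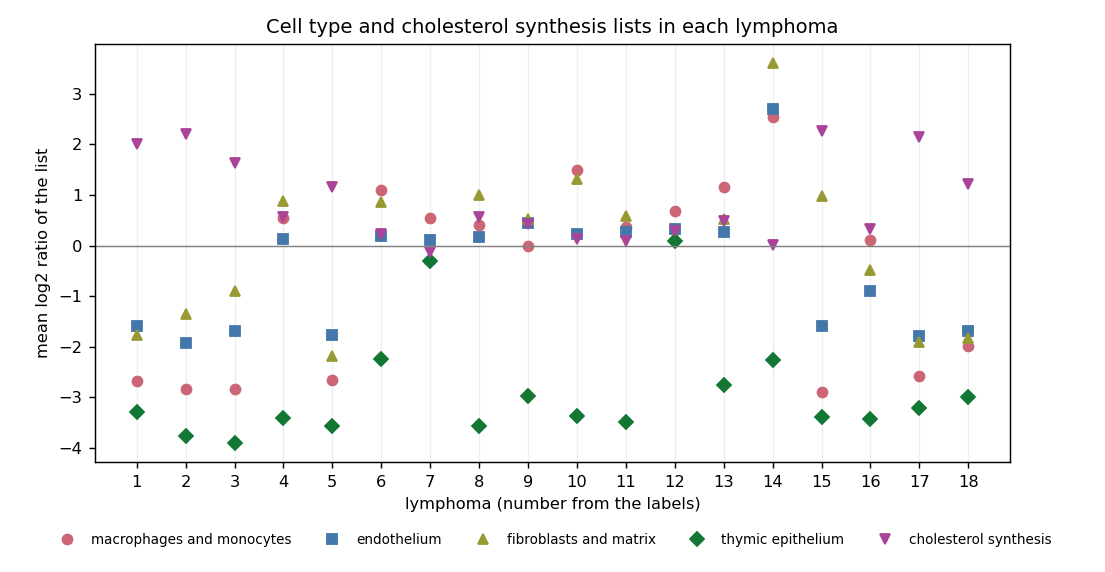
Mean log2 ratio of the macrophage, endothelium, fibroblast, thymic epithelium and cholesterol synthesis lists (vertical axis) in each of the 18 lymphomas (horizontal axis). The macrophage list lies at -1.99 or lower in lymphomas 1, 2, 3, 5, 15, 17 and 18, and the thymic epithelium list lies at 0.09 in lymphoma 12 and at -0.30 or lower in the others.

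Expression also varied by chromosomal position. After each gene's median over the lymphomas was removed, 217 of 360 chromosome medians differed from genes drawn across chromosomes (permutation test, 10000 draws, smallest possible p = 1e-04), 107 higher and 110 lower, but their median size was only 0.07 on the log2 scale. The largest was 0.29. That test treats genes as independent and leaves out genes regulated together. Neighbouring genes correlated across the lymphomas with a mean r of 0.164, against at most 0.00810 in 100 shuffled orders, and genes 20 places apart still had a mean r of 0.0606, against at most 0.00630 (p = 0.0099 for both, the smallest that 100 shuffles can give).

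In 17 of the 18 lymphomas, windows of 11 neighbouring genes lay beyond every window of 100 shuffled gene orders, giving 58 runs, 44 higher and 14 lower. A run is taken relative to each gene's median over lymphomas and can span genes that moved the other way. On chromosome 10, 18 of the 26 genes in a run from Abracl to Sgk1 were higher in lymphoma 5, with a median of 2.62 at the strongest window, and this run spans Perp, Ifngr1 and Myb. Myb was at 0.06 in lymphoma 5 and below 0 in the other 17. In lymphoma 2, 23 of 32 genes in a run on chromosome 10 and 11 of 12 in another across Myb were higher (1.29 and 1.23), and in lymphoma 4, 16 of 18 genes in a run from Nhsl1 to Gm20149, which stops before Myb, were lower (-1.09). On chromosome X, overlapping runs from the Bex and Tceal gene region were higher in lymphomas 11 (29 of 34 genes, 2.30), 16 (28 of 31, 2.12) and 1 (19 of 24, 1.79). On chromosome 2, runs that span Notch1 were higher in lymphomas 18 (17 of 20 genes, 1.96) and 15 (13 of 16, 1.88), the lymphomas with the highest Notch1 ratios, 6.28 and 5.24. Other runs of higher genes lay around Fgfr1 on chromosome 8 in lymphoma 8 (27 of 30 genes, 1.47) and from Rab1a to Rel on chromosome 11 in lymphoma 4 (21 of 27, 1.26). Copy number of DNA was not analysed here.

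**Figure D4:**
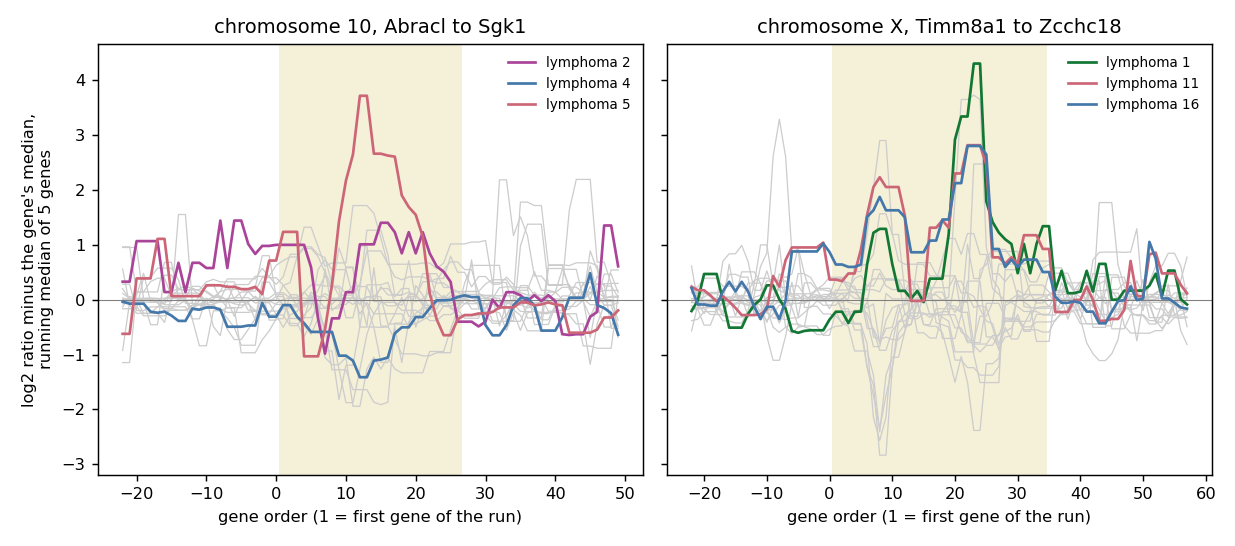
Running median over 5 genes of the log2 ratio minus the gene's median over the 18 lymphomas (vertical axis) in gene order (horizontal axis), for chromosome 10 around Abracl to Sgk1 with lymphomas 2, 4 and 5 coloured, and for chromosome X around Timm8a1 to Zcchc18 with lymphomas 1, 11 and 16 coloured. Grey lines are the other lymphomas and shading marks the run, whose strongest window reaches 2.62 in lymphoma 5 and 2.30 in lymphoma 11.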

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

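Leaving out lymphomas 7, 12 and 14 or lymphomas 1, 2, 3, 5, 15, 17 and 18 was chosen after seeing the data, and all other alternatives were fixed before. No paired analysis was possible because the samples form 1 group. Over 287 single genes and lists, 8642 of 8858 recalculated values kept their side of the threshold and, where they passed, their direction. Of the rest, 112 (55 results) no longer passed, 92 (29 results) newly passed and 12 that passed before or after changed sign. A change of sign in a value that passed neither before nor after counts as kept.

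Leaving out each lymphoma in turn, the genes changed numbered 10080 to 10912 (5164 to 5591 higher, 4891 to 5321 lower), those changed at least 2-fold 2668 to 2942 (747 to 859 higher, 1909 to 2103 lower) and the lists passing 20 to 22 (7 to 7 higher, 13 to 15 lower). At the level of single probes, where more tests are made, 16841 passed (8800 higher, 8041 lower), 4554 of them at least 2-fold (1387 higher, 3167 lower). A threshold of 1.5-fold gave 5708 genes (2355 higher, 3353 lower), and testing against 2-fold with treat in limma gave 873 (159 higher, 714 lower). With an estimated correlation in camera 0 lists passed (0 higher, 0 lower). Without lymphomas 1, 2, 3, 5, 15, 17 and 18, the genes called higher fell to 3556 with fewer samples. With the sign turned, Atm would be at 0.65 and Terc at 1.47. With 1 probe per gene in place of the mean, Trp53bp1 changed to -0.14, Phf6 to 0.51, Bad to 0.41 and Sox17 to 0.12, and the cause was not tested. Without the 7 lymphomas chosen for few macrophage markers, Pf4 was at 2.26, Clec7a at 0.31, Wfdc17 at 1.52, Ctsh at 0.17, Lyz2 at 0.16, Kdr at 0.010 and Cldn5 at 0.088, and the macrophage list was higher than other genes (adjusted p = 0.00676), as the choice of samples brings about. The count of chromosome medians was 218 with arrays centred and 216 over complete genes.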

Other observations

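The correlations with Notch1 and the split before them, the lymphomas singled out and the tests of array scale, macrophages and vessel cells, other lists in the same lymphomas, fibroblasts, a mislabelled sample, cancelled dye swaps, narrowed ratios, thymus tissue and gene families were chosen after the results had been seen. The test of genes regulated together was set before its result was seen.

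Some lymphomas stood apart by whole groups of genes. Lymphomas 7 and 14 had the lowest means of the double-positive thymocyte list, -3.60 and -3.72, with Dntt, the terminal transferase of thymocytes, at -6.40 and -4.52, and with Notch1 at -0.79 and 0.08. In lymphoma 7 the basal keratin gene Krt5 was at 2.62 and a run of keratin genes on chromosome 15 was 4.15 above its median over lymphomas, as was a run of kallikrein genes on chromosome 7, by 3.27. In lymphoma 14 the means of the fibroblast, endothelial, macrophage and striated muscle lists were 3.61, 2.71, 2.54 and 3.11, and that of T cell receptor signalling was -3.08. The skeletal actin gene Acta1 was at 5.33 in lymphoma 14 and at 5.10 in lymphoma 11. The glycolysis list mean was 2.38 in lymphoma 15. Ikzf1, which encodes the transcription factor Ikaros, fell by 1.13 on average (SD 1.51, n = 18) and was lowest in lymphomas 16 (-4.66), 11 (-4.29) and 14 (-2.89). Its 2 probes differ, with means of -1.93 and -0.32, and in lymphoma 4 they read -5.79 and 1.99. Lymphomas 11 and 16 also shared the run on chromosome X and had the highest correlation of any pair, 0.816 over all probes.

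Notch1, Dtx1 and Ptcra were lowest in the same 3 lymphomas, while the target Nrarp was not. Lymphomas 7, 8 and 14 had the lowest ratios of Notch1 (-0.79, -1.84 and 0.08), of Dtx1 (-1.91, -2.65 and -1.25) and of Ptcra, the chain that pairs with the T cell receptor beta chain in immature thymocytes (-4.43, -4.02 and -3.58, against -0.67 or higher in the other 15). Over all 18, Notch1 correlated by rank with Dtx1 (rho = 0.721), Ptcra (0.701), Hes1 (0.579), Myc (0.571) and Il2ra (0.517), with adjusted permutation p-values of 0.0348 or less. Nrarp did not correlate (rho = 0.096, adjusted permutation p = 0.706). The 3 lymphomas below the gap can carry such correlations, while leaving them out narrows the range of Notch1. Lymphomas 7 and 14 also had the lowest double-positive thymocyte list means (-3.60 and -3.72). Differences in cell content are therefore not separated from these correlations. Among the other 15, 6 relations with Notch1 were computed, and Dtx1 correlated by Pearson's r (0.735, permutation p = 0.00207, adjusted 0.0124) but not by rank (rho = 0.518, permutation p = 0.0507, adjusted 0.208). Without lymphomas 12 and 4, farthest from the median of Notch1, r fell to 0.373, so the relation rests on those lymphomas. For Hes1, Ptcra, Il2ra, Nrarp and Myc, r was 0.365, 0.404, 0.182, 0.279 and 0.429 and rho 0.314, 0.486, 0.293, 0.239 and 0.350, with adjusted permutation p-values of 0.269 or more for r and 0.208 or more for rho.

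Sex-linked genes did not follow a common pattern. The Y-linked Eif2s3y was near the reference in lymphomas 2 (-0.48), 5 (0.61) and 15 (-0.65), between -3.85 and -2.03 in lymphomas 6, 7 and 8, and at -4.73 or lower in the others. Over all 18, Kdm5d was at -3.48 ± 1.90 and Uty at -1.48 ± 0.78. In lymphoma 15 Kdm5d was at -0.17, but the Uty probes measured on all arrays read -2.11, -0.52 and -1.51. Xist, the RNA of the inactive X chromosome, was at -0.13 or above in lymphomas 4, 9, 10, 12, 13, 14 and 18, up to 3.17, and at -2.72 or lower in the other 11. In lymphomas 1, 3, 6, 7, 8, 11, 16 and 17 both Eif2s3y and Xist were low. The labels give no sex.

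Macrophage markers were far lower in lymphomas 1, 2, 3, 5, 15, 17 and 18 than in the other 11, with a gap of 1.98 between the list means. Array scale alone is argued against by the list means, -1.99 or lower in the 7 and -0.01 to 2.54 in the other 11. A positive factor per array leaves such means apart, so the gap of 1.78 after scaling was bound to stay and adds nothing. After quantile normalization, which keeps the order of genes on each array, the gap was 1.68. Fewer macrophages and vessel cells may account for the pattern, since the endothelial list, which shares no gene with the macrophage list, separated the same lymphomas by 0.686, as did the adipocyte list by 0.63 and the dendritic cell list by 0.27, while cholesterol synthesis was higher in the 7 by 0.58. Fewer fibroblasts stay open too, but the fibroblast list means of all 7 overlapped those of the other 11 (gap of -1.46). In 6 of the 7 they lay lower by 0.411, but these 6 were picked for that, so the gap is no test. In lymphoma 15 the mean was 0.97, above the lowest of the other 11 (-0.49), with 6 of 14 genes below their median in those 11. This decides nothing. Apart from the cell content of the samples, no biological explanation was tested, because the design gives 1 group, and how the tissue was taken is not known.

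In lymphoma 12 the thymic epithelium list mean was 0.09, against -3.90 to -0.30 in the others, and the adipocyte list mean was 0.79, against -4.37 to -1.43. A sample that is not a knock-out stays open. Terc was at -2.15 in lymphoma 12 (median of the others -1.53), and the Atm probes were at -0.98 and -1.02. Whether the Terc and Atm probes lie in the deleted parts is not known, so these low ratios do not decide. Ratios cancelled between the dye-swapped arrays are argued against by the mean of Eif2s3y, Kdm5d and Terc, -3.51. Scaling of arrays is no test of narrowed ratios, since a factor per array keeps the sign of a list mean. After scaling, the thymic epithelium list was at 0.161 in lymphoma 12 and at -0.39 or lower in the others. For the same reason, narrowing alone would not turn the sign of that list mean, which was 0.09 before scaling. Thymus tissue in the sample may account for it, but the values do not decide, since the double-positive thymocyte list was at -0.599 (median of the others -1.40) and Notch1 and Cdkn2a were raised less (1.59 and 2.19, medians of the others 4.06 and 3.68), while this array had the smallest SD, 0.58 against 0.91 to 1.30, and after scaling the list (-1.16, median -1.44) and Notch1 (3.01, median 3.85) kept their side but Cdkn2a (4.16) lay above its median. Apart from the cell content of the sample, no biological explanation was tested.

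The runs of neighbouring genes in single lymphomas include gene clusters, such as the keratins in lymphoma 7 and the C-type lectin and complement genes on chromosome 6, lower in lymphomas 1, 2, 5, 15 and 17, all among the 7 with few macrophage markers, and higher in lymphoma 10 (1.30). Regulation of a cluster as a unit was not decided. Of the 58 runs, 33 did not correlate in the other 17 lymphomas above the 95th percentile of windows of 11 genes. A cluster raised in 1 lymphoma alone need not correlate in the others, so this does not argue against such regulation. The 33 include the keratin run of lymphoma 7 (mean r 0.120 against 0.267) and the chromosome 10 run of lymphoma 5 (0.222 against 0.278). Overlapping chromosome 10 runs in lymphomas 2 (0.462 against 0.271) and 4 (0.308 against 0.274) did correlate above it. For the 25 runs above the percentile, regulation of a cluster may be the cause, although a run shared by several lymphomas raises that correlation by itself, as on chromosome X. Differences in cell content between the samples can raise it too, and they were not tested for the runs. Shared hybridisation within a gene family is argued against as a general cause by symbols, as in only 7 of 58 runs did at least 6 of 11 genes share a stem. A change in DNA copy number stays open as an untested hypothesis, since DNA was not analysed here.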
